A study of Mus musculus with 6 samples.

How the data were processed

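Whole dorsal skin of male C57BL/6 mice, a wild-type inbred strain, was dissociated and profiled by droplet single-cell RNA sequencing at 8, 26 and 52 weeks of age. At each age 1 library was made from untreated skin, which went straight to dissociation. A further library was made from skin treated ex vivo with PBMC-sec, the mixture of factors that gamma-irradiated mononuclear blood cells release. Per the labels, every library pooled 3 animals, and all 6 libraries went through the same dissociation kit. The labels give neither the dose nor the length of the treatment, nor do they say whether the treated and the untreated library of an age shared animals. Treated skin was held outside the body and untreated skin was not, so the PBMC-sec contrast measured both together.

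Per the file headers, the deposited matrices hold whole-number UMI counts per gene and cell barcode, written by Cell Ranger 5.0.1 and not normalised. The other deposited files list the cell barcodes and the 32285 genes by Ensembl identifier and symbol. Per the labels, the libraries were made with the Chromium Single Cell 3′ kit, version 3.1. Per the submitters' processing notes, reads were mapped to mm10 (GRCm38). The release of the gene annotation is not given in the sources used here, and gene positions were taken from GENCODE vM21 on GRCm38 by Ensembl identifier. The deposited barcodes had already been called as cells. Of the members of the fixed gene lists, 3 were not analysed here.

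Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. Scrublet scored doublets within each library, but its automatic threshold called 0 barcodes in every library. The barcodes with the highest scores were therefore removed at a rate of 0.8% per 1000 barcodes, a rule set after that result was seen. It removed 703, 251, 257, 293, 120 and 208 barcodes in the order 8-week untreated, 8-week PBMC-sec, 26-week untreated, 26-week PBMC-sec, 52-week untreated and 52-week PBMC-sec, which is the order of all lists of 6 values below. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries, and 30 principal components with 20 nearest neighbours gave Leiden clusters at resolution 1, with no batch integration. Clusters of mononuclear phagocytes were clustered again by themselves.

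Clusters were named from marker genes fixed before the data were examined. The scoring of these markers was set after the clusters had been seen. Each class was scored over its 8 best markers, and a class with a score under 0.55 or with under 3 raised markers was passed over for the next-best one. A cluster took the name of the first class left, so a class with a higher score could be passed over, as in macrophage sub-cluster 1 (278 cells, macrophage 0.629, mast cell 0.774). It stayed unnamed where no class was left, where a class of another lineage scored above 0.8, or where its 10 leading genes held more markers of another class. The same held where its UMIs were low and those 10 genes held no marker. Names are used in the sense of "macrophage-like". No cluster reached the monocyte, mast cell or B cell classes.

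Free RNA adds transcripts of abundant cells to every droplet. A gene was called prone to free RNA in a class if its CPM over all other cells exceeded 5 times its CPM in the class in any library. Within the 8-week untreated library many barcodes shared near-identical profiles. Each library was clustered finely by itself (Leiden resolution 5), and clusters of at least 10 barcodes whose Pearson dispersion around 1 shared profile was at most 2 were marked as repeated. These barcodes were kept, and an alternative without them was added after the data were seen, before any gene was tested. It removed 3025 barcodes (35.4%) of the 8-week untreated library and 42, 0, 0, 25 and 37 of the others.

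Cells were not treated as replicates. Raw UMI counts were summed per class and library, and classes with at least 30 cells in every library were tested, which left 6: macrophages, T or innate lymphoid cells, fibroblasts, keratinocytes, pericytes or smooth muscle cells, and vascular endothelial cells. edgeR's quasi-likelihood test with TMM factors and filterByExpr was fitted to the 6 libraries with age and treatment as factors, leaving 2 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested in the class, with a threshold of 0.05. Fold changes are log2 values with standard errors taken from the log2 change and the F statistic, and left out where that statistic is near 0. Every library is a pool and each condition has 1 library, so the residual spread of this fit is that of the treatment difference between ages. The p-values do not measure a spread between replicate libraries or between animals. In the age test the 2 libraries of an age served as its samples. They may share animals, so its p-values may rest on 1 pool of animals per age. The age contrast set 52 against 8 weeks with treatment as a block. A separate fit tested whether the PBMC-sec difference changed linearly with age in weeks.

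Before the data were examined, 25 gene lists were fixed, and lists with at least 5 members tested in a class entered limma's camera with a preset correlation of 0.01, on log2 CPM with a prior count of 2, adjusted over the lists of the class. Camera with an estimated correlation and fry were alternatives. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals, summed counts carry exact Poisson 95% intervals, and both cover counting error only. A count of 0 is given with an upper limit of 3 counts. Treated-to-untreated log2 ratios of shares were tested over the 3 ages with an exact two-sided sign-flip permutation test, whose smallest p is 0.25. The 3 untreated libraries alone had no replicate, so their values by age are given without a test.

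The rule for named genes was fixed before the data were examined. For macrophages it took the 10 genes with the largest change in each direction among those past the threshold with a mean log2 CPM of at least 5 and the same direction in every pair. It added up to 4 members of each list past the threshold, or the 2 most highly expressed members where none passed, and Mrc1, Cd163, Lyve1, H2-Ab1, Il1b, Ccl2, Arg1 and Cdkn1a whatever their result. Other classes gave 5 genes per direction. Mitochondrial genes, ribosomal protein genes, unnamed gene models and genes prone to free RNA were left out of the choice by size of change. For the untreated libraries it took 10 genes per direction with at least 100 UMIs in all, at least 10 in the higher library and the 26-week value between the others. Genes outside the rule are named as such. Some genes that the rule names are not reported here.

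The test was checked on simulated counts drawn from the real means and library sizes with 200 changed genes. In macrophages, 37.1% of 2-fold and 96.6% of 4-fold changes were recovered for treatment over 1975 genes, 9.78% and 78.7% for age over 1966 genes, and 2.17% and 3.37% for the change of the treatment difference with age over 1991 genes.

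Alternatives fixed beforehand were RLE size factors, DESeq2, no filter on low counts, sums thinned to the smallest total, genes prone to free RNA left out, mitochondrial limits of 5% and 20%, doublets kept, Leiden resolution 2, all mononuclear phagocytes pooled, no block, other codings of age, and each pair or library left out. Alternatives added after the data were seen were the removal of repeated barcodes, the inclusion of unnamed phagocyte sub-clusters, and for the other classes each library left out of the age test, both other list tests, and lists under the alternatives used for genes, with each pair or library left out. Macrophage shares without sub-cluster 1 were added too. The fit of treatment by age in classes other than macrophages was also added then. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.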

Results

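Whole dorsal skin of male C57BL/6 mice was profiled by droplet single-cell RNA sequencing, in a series whose title asks how the phenotype and function of skin macrophages change with age. Skin of mice aged 8, 26 and 52 weeks was sequenced untreated or after ex vivo treatment with PBMC-sec, the factors released by gamma-irradiated mononuclear blood cells. There were 6 libraries, 1 per age and treatment, each a pool of 3 animals. Values for the 6 libraries are given in the order 8-week untreated, 8-week PBMC-sec, 26-week untreated, 26-week PBMC-sec, 52-week untreated and 52-week PBMC-sec. The deposited matrices held 9520, 5739, 5766, 6182, 4083 and 5252 barcodes with 23799097, 23781709, 19956655, 32349167, 20220672 and 40211991 UMIs. After filtering, 8534, 5208, 5322, 5631, 3566 and 4741 cells remained, with medians of 1166, 2635.5, 2224, 3474, 3090.5 and 4832 UMIs per cell. Treated libraries were deeper per cell than untreated ones at every age. Keratinocytes were the most frequent class, with 80.4, 66.5, 58.7, 65.6, 48.6 and 62.4% of cells, followed by fibroblasts with 8.99, 17.1, 24.99, 20.6, 28.2 and 18.9%. Cells left unnamed made up 2.13, 4.40, 5.71, 3.14, 3.90 and 4.79%. The largest unnamed cluster held 175, 226, 303, 174, 84 and 97 cells. Its 10 leading genes included Hspa5, Manf, Herpud1 and Ddit3, members of the unfolded protein response list. That list was therefore tested in every class below without these cells.

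The first comparison asked how frequent macrophages were. Macrophage-like cells, defined by markers such as C1qb (a complement component) and Pf4 (a chemokine of resident macrophages), formed a larger share of the skin cells at 52 weeks than at the younger ages. They made up 0.996% (95% interval 0.796 to 1.23), 1.61% (1.29 to 1.99), 1.28% (0.994 to 1.62), 1.39% (1.10 to 1.73), 11.02% (10.0 to 12.1) and 5.57% (4.93 to 6.26) of cells, from 85, 84, 68, 78, 393 and 264 cells. The share at 52 weeks was 11.1 times that at 8 weeks in untreated skin and 3.45 times in treated skin, and of immune cells alone it was 2.49 and 1.91 times. The exact binomial intervals cover counting error only, there was 1 library per condition, and median depth in these cells was also highest at 52 weeks, with 1224, 1368.5, 1001, 1367.5, 1931 and 2878 UMIs. With PBMC-sec the share changed by log2 0.70 at 8 weeks, 0.12 at 26 weeks and -0.98 at 52 weeks, a mean of -0.06 ± 0.85 (SD, n = 3 pairs, exact sign-flip permutation p = 1). The 8-week untreated library held many near-identical barcodes, and without such barcodes these 3 values were 0.30, 0.04 and -0.92 and the 52-to-8-week ratios 8.57 and 3.70. Without sub-cluster 1, whose name is less certain, the 52-week shares were 5.41% (4.69 to 6.21) untreated and 4.75% (4.16 to 5.39) treated. The 3 log2 values were then 1.03, 0.11 and -0.19 (mean 0.32 ± 0.64, SD, n = 3 pairs, exact sign-flip permutation p = 0.75) and the age ratios 7.57 and 3.25.

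**Figure D1:**
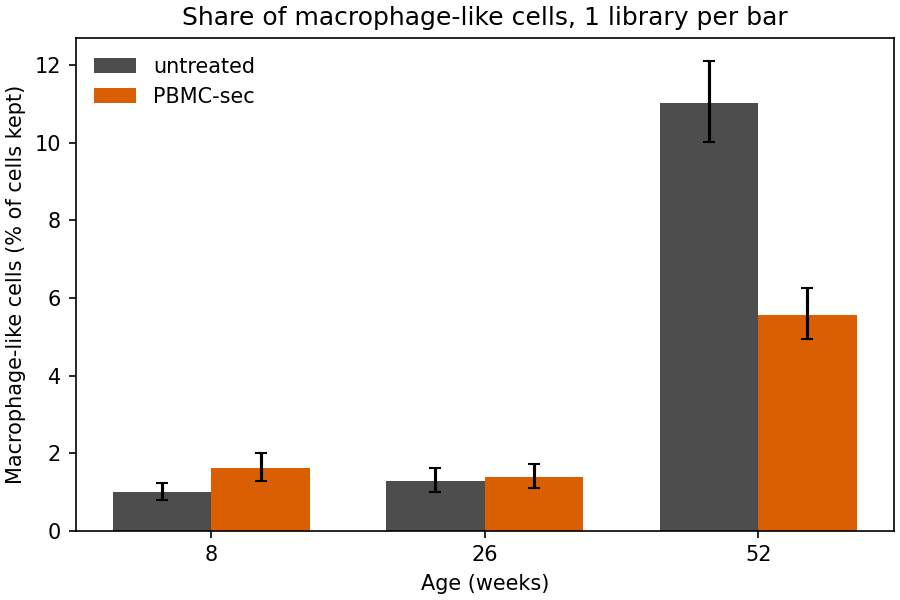
Macrophage-like cells as a percentage of all cells in each of the 6 libraries, with exact binomial 95% intervals. The 52-week untreated library stood at 11.02% and the 52-week PBMC-sec library at 5.57%, while the 4 younger libraries lay between 0.996 and 1.61%.

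The macrophages fell into 5 sub-clusters, numbered 1, 2, 3, 5 and 7, whose weights differed between libraries. Sub-cluster 2, led by Pf4, Ccl12 and Ccl8, held 45.9, 42.9, 75, 51.3, 12.0 and 23.9% of macrophages. Sub-cluster 1, led by Arg1 and Clec4d, held 28.2, 9.52, 4.41, 5.13, 50.9 and 14.8%. Its 278 cells had a macrophage score of 0.629 and a mast cell score of 0.774. The latter class was passed over because under 3 of its markers were raised, so the name of this sub-cluster is less certain. Sub-cluster 3, led by Ccl4, Tnf and Il1b, held 9.41, 41.7, 11.8, 38.5, 12.0 and 33.0%. Sub-cluster 5, led by Pf4 and Ccl9 and with the interferon gene Rsad2 among its 10 leading genes, held 11.8, 2.38, 7.35, 2.56, 12.0 and 18.6%. Sub-cluster 7, which carried Trem2 (a lipid receptor of macrophages), held 4.71, 3.57, 1.47, 2.56, 13.2 and 9.85%. These genes define the sub-clusters and are not results. Every value within macrophages below mixes changes inside sub-clusters with these shifts in their weights, and the 2 largest sub-clusters of a library were not the same throughout.

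The second comparison set treated against untreated macrophages over all 3 ages. Only treated skin was held ex vivo, so every PBMC-sec difference below holds treatment and holding together. In treated macrophages Akr1b3, which encodes aldose reductase, and Fxyd2, a regulatory subunit of the sodium-potassium pump, showed the largest rises among genes measured above the free-RNA limit. Akr1b3 rose from 64.9 to 1306 CPM at 8 weeks, from 118 to 1187 at 26 weeks and from 75.4 to 1037 at 52 weeks, a log2 change of 3.94 ± 0.30 (SE, adjusted p = 0.000694). Fxyd2 rose from 117 to 2287, from 203 to 1569 and from 29.8 to 806 CPM (log2 4.18 ± 0.39, adjusted p = 0.00129), and it was among the 10 leading genes of sub-cluster 2. H1f0, a linker histone of non-dividing cells, rose from 110.4 to 628, from 42.8 to 474 and from 114 to 326 CPM (log2 2.38 ± 0.37, adjusted p = 0.0324). The protease inhibitors Slpi, which blocks neutrophil elastase, and Serpinb2, which blocks urokinase, rose by log2 2.29 ± 0.32 and 1.74 ± 0.23 (adjusted p = 0.0207 and 0.0166). Slpi went from 357 to 2849.7, from 791 to 3315 and from 2131 to 6032 CPM, and Serpinb2 from 844 to 2547, from 1283 to 3498 and from 746 to 2532 CPM. On GRCm38, Akr1b3 (ENSMUSG00000001642) lies on chromosome 6 at 34302434 to 34317478, Fxyd2 (ENSMUSG00000059412) on chromosome 9 at 45399669 to 45410278 and H1f0 (ENSMUSG00000096210) on chromosome 15 at 79028450 to 79030504. Slpi (ENSMUSG00000017002) lies on chromosome 2 at 164354070 to 164389095 and Serpinb2 (ENSMUSG00000062345) on chromosome 1 at 107511423 to 107535478, all as whole gene spans. These were 5 of the 9 genes that passed edgeR's quasi-likelihood test among 2133 tested, all 9 higher and 0 lower. At an unadjusted p under 0.05 there were 235 genes, and DESeq2 called 18 higher and 4 lower.

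Other called genes were prone to free RNA in these cells, having over 5 times their macrophage CPM in the remaining cells of some library. Mmp9, a gelatinase, had 0, 28, 6, 33, 4 and 105 UMIs (adjusted p = 0.0324). U90926 had 0, 9, 0, 28, 1 and 144 UMIs and the mast cell protease gene Mcpt4 had 0, 0, 1, 22, 9 and 114 UMIs, and both fall outside the rule for named genes and were picked after their values were seen. The fitted folds of these 3 genes are not given, since some libraries held 0 UMIs. Slpi and Mmp9 also stood on the neutrophil marker list, and Mcpt4 on that of mast cells. Without the 8-week pair the adjusted p was 0.0831 for Slpi (log2 1.91) and 0.0927 for Serpinb2 (log2 1.75). Without the 26-week pair it was 0.0893 for H1f0 (log2 2.13), and without the 52-week pair 0.106 for Mmp9. These fits had fewer libraries and 1 residual degree of freedom. Over all alternatives the adjusted p ranged up to 0.228 for Slpi, 0.0927 for Serpinb2, 0.0893 for H1f0 and 0.130 for Mmp9. The count went from 9 to 20 without the 8-week pair (15 higher, 5 lower), to 8 without the 26-week pair (7 and 1) and to 24 without the 52-week pair (12 and 12), so the rises did not prevail in every fit.

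**Figure D2:**
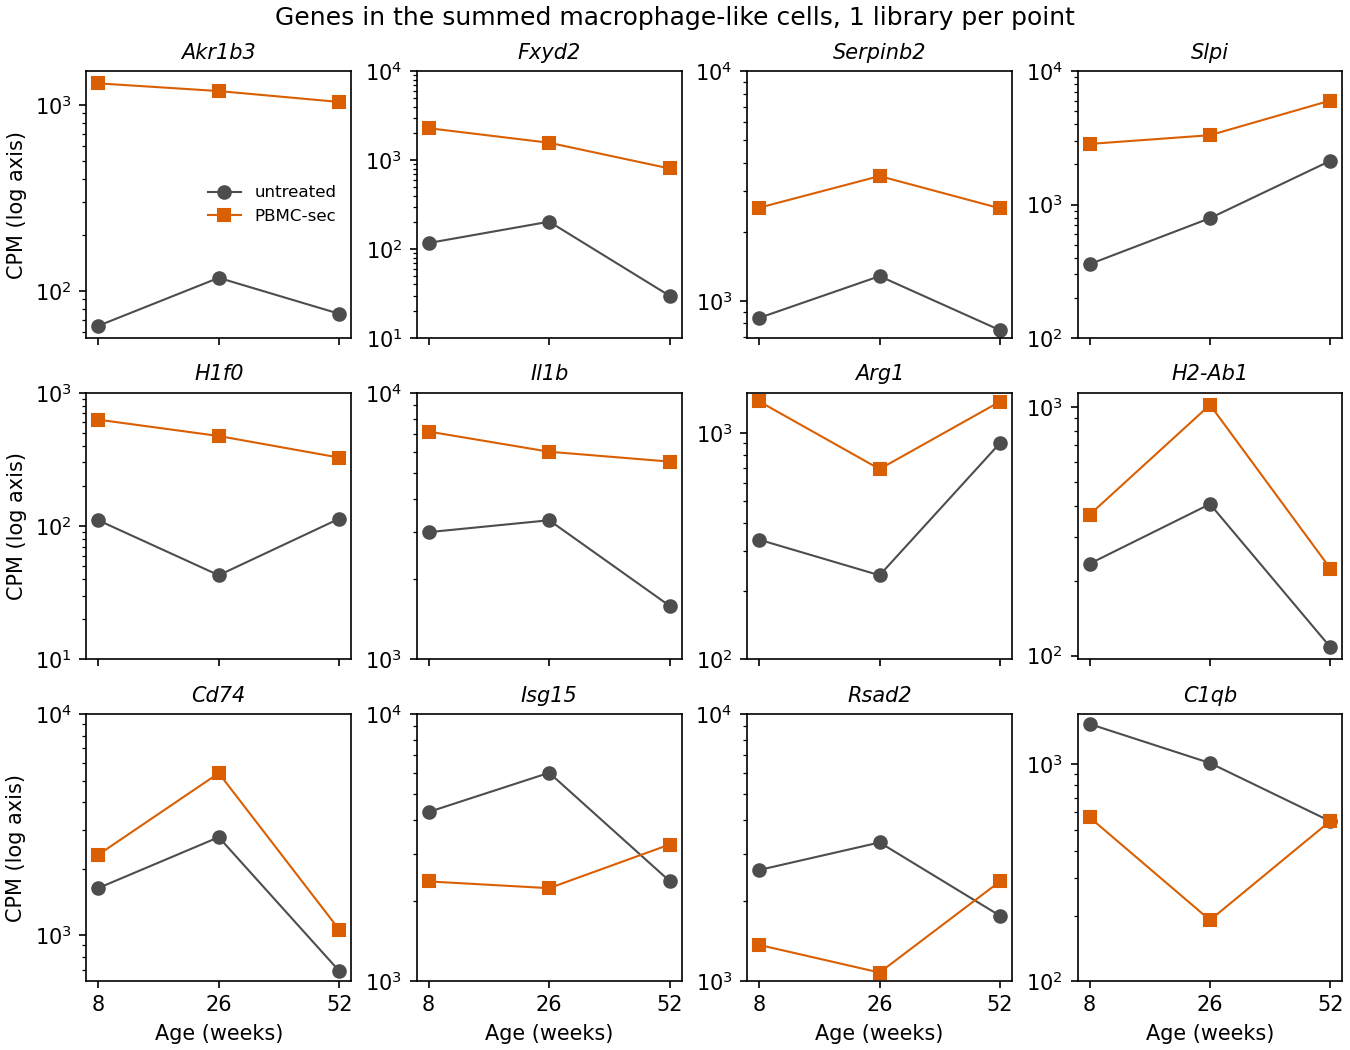
CPM in macrophages of each library, on a log axis. Shown are the 5 genes that passed the treatment test under the rule for named genes (Akr1b3, Fxyd2, Serpinb2, Slpi and H1f0). Also shown are Il1b, Arg1, H2-Ab1, Cd74, Isg15, Rsad2 and C1qb, which did not pass. For the 5 genes that passed, the PBMC-sec library lies above the untreated one in each age pair. For Akr1b3 the values at 8 weeks were 64.9 CPM untreated and 1306 CPM treated.

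Among the gene lists fixed beforehand, 8 of the 19 tested in macrophages passed camera for treatment. The type I interferon list, genes that cells switch on after interferon signalling, was lower with PBMC-sec, with a median log2 change of -0.87 over 21 members (adjusted p = 4.75e-07, adjusted p = 0.628 with an estimated correlation). None of its members passed by itself, whether adjusted over all genes (0) or adjusted over the list alone (0). Its mean log2 CPM was 8.94 untreated and 7.44 treated at 8 weeks, 9.12 and 6.88 at 26 weeks, and 8.18 and 8.34 at 52 weeks. Bst2, a tetherin that holds back budding viruses, had a log2 change of -1.46 ± 0.36 (adjusted p = 0.154) and was picked after its value was seen. Isg15, a ubiquitin-like modifier, and Rsad2, viperin, had -0.48 ± 0.35 and -0.56 ± 0.37. The class I presentation list was also lower (9 members, median -0.30, adjusted p = 0.0140, adjusted p = 0.628 with an estimated correlation), with 0 members past the threshold either way and B2m, the light chain of class I molecules, at -0.77 ± 0.27. That call was lost without the 8-week pair (adjusted p = 0.228) or the 26-week pair (0.154), over alternatives ranging from 0.00305 to 0.628. For the unfolded protein response, the chaperones and signals induced when proteins misfold in the endoplasmic reticulum, the median over 12 members was -0.66 (adjusted p = 0.000172, adjusted p = 0.582 with an estimated correlation). Its members Hspa5, the chaperone BiP, and Ppp1r15a, a phosphatase subunit that restores translation, had -0.63 ± 0.33 and -0.67, with 0 past the threshold. The immediate early and dissociation stress list had a median of -0.30 over 19 members (adjusted p = 0.00541, adjusted p = 0.628 with an estimated correlation). Its most abundant members were near 0, Ier3 at 0.03 and the mRNA decay factor Zfp36 at 0.03, 0 members passed, and the call was lost without the 8-week pair (0.0622) or the 26-week pair (0.297), with thinned sums (0.0553), with all mononuclear phagocytes pooled (0.588) or with unnamed sub-clusters included (0.207), over alternatives from 0.00592 to 0.628.

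**Figure D3:**
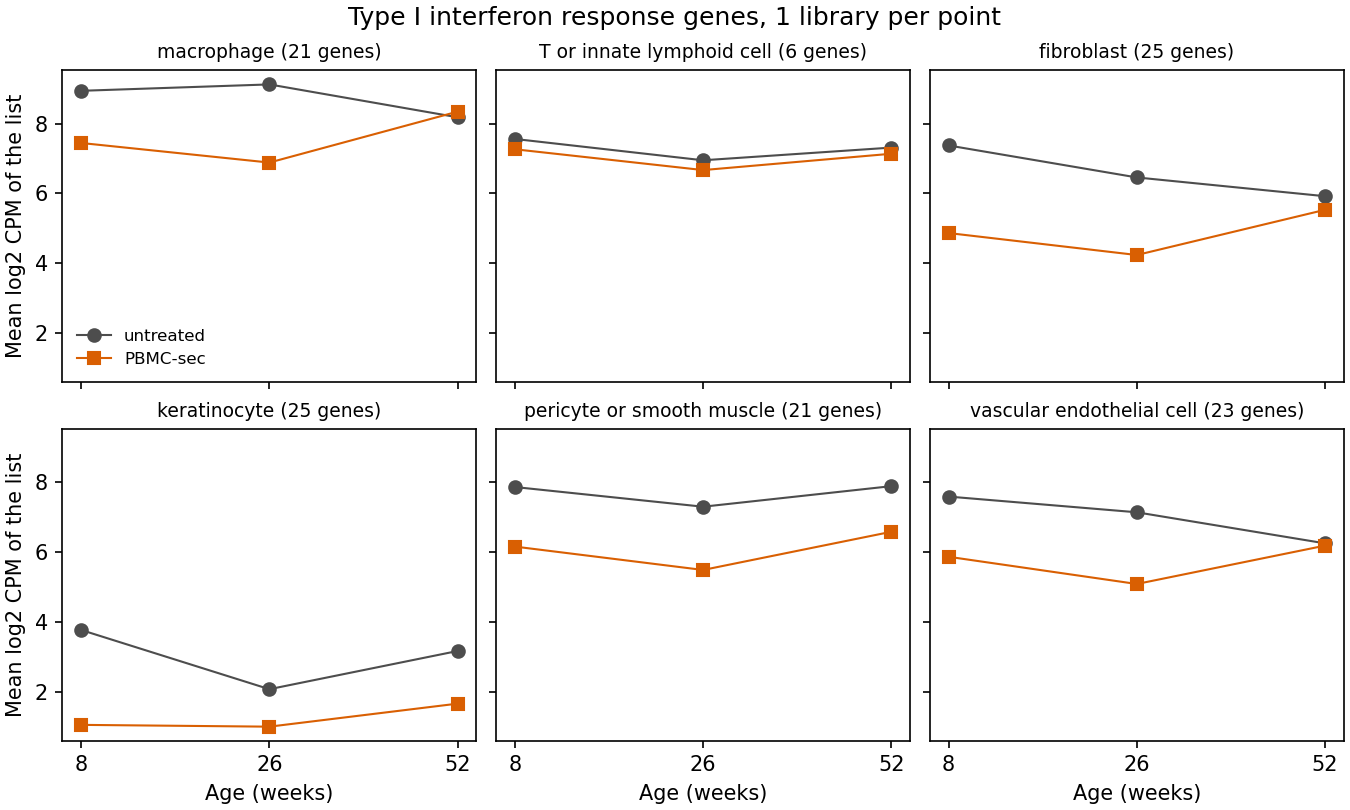
Mean log2 CPM of the type I interferon list in each library for the 6 classes tested. In macrophages the treated library lay below the untreated one at 8 weeks (7.44 against 8.94) and 26 weeks (6.88 against 9.12), and at 52 weeks the values were 8.34 and 8.18. In endothelial cells the 52-week values were 6.19 treated and 6.26 untreated.

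The other 4 lists that passed were higher with PBMC-sec. The matrix protease list had a median log2 change of 0.59 over 15 members (adjusted p = 6.96e-05, adjusted p = 0.626 with an estimated correlation), with 3 members higher over all genes, Serpinb2 and Mmp9 among them, and 5 adjusted over the list alone. The members of this list that moved include inhibitors of proteolysis as well as a protease. The NRF2 list, antioxidant genes such as Slc7a11, the cystine transporter, and Fth1, the ferritin heavy chain, had a median of 0.49 over 19 members (adjusted p = 6.96e-05, adjusted p = 0.582 with an estimated correlation). Of these 0 passed over all genes and 5 adjusted over the list alone, with Slc7a11 at 1.35 ± 0.28 (adjusted p = 0.101), Gsr, glutathione reductase, at 1.27, Fth1 at 0.66 and Ftl1, the ferritin light chain, at 0.18. The inflammatory list of cytokines and chemokines had a median of 0.43 over 22 members (adjusted p = 6.96e-05, adjusted p = 0.626 with an estimated correlation), with 0 past the threshold over all genes and 5 higher adjusted over the list alone. Il1b, an inflammatory cytokine, went from 3000.2 to 7149.6, from 3325 to 6007 and from 1587 to 5517 CPM, a log2 change of 1.44 ± 0.25 that missed the threshold (adjusted p = 0.0628). Over 16 alternatives of the gene test its adjusted p ranged from 8.18e-06 to 0.401, at log2 changes of 1.15 to 1.73. Ptgs2, the inducible prostaglandin synthase, had 1.33 ± 0.25 (adjusted p = 0.0691), whereas the chemokines Cxcl2, Ccl4 and Ccl2 had 0.41, 0.36 and -0.27. Slc7a11, Gsr and Ptgs2 lie outside the rule for named genes and were picked after their values were seen. Il1b was a leading gene of sub-cluster 3, whose weight was higher in each treated library. Without the 52-week pair the list's median was 0.06 and its adjusted p 0.116, over alternatives from 3.54e-07 to 0.626. The class II presentation list, which loads antigen for helper T cells, had a median of 0.99 over 6 members (adjusted p = 0.0447, adjusted p = 0.626 with an estimated correlation). Of its members 0 passed over all genes, and 4 were higher and 1 lower adjusted over the list alone. H2-Ab1 had 1.15 ± 0.26, the invariant chain Cd74 0.83 ± 0.22, and the lysosomal protease Ctss -0.69. That call was lost without the 8-week (0.0757), the 26-week (0.0731) or the 52-week pair (0.116), and at 5% mitochondrial UMIs (0.105), with doublets kept (0.299) or at Leiden resolution 2 (0.0584), over alternatives from 0.000251 to 0.626. No macrophage list passed with an estimated correlation or with fry, for which the counts were 0 and 0.

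The remaining 11 lists did not pass for treatment. Median log2 changes were 0.14 for perivascular resident macrophage genes (adjusted p = 0.486), with the mannose receptor Mrc1 at 0.33 ± 0.33, Pf4 at 0.17 and the chemokine Ccl8 at -0.39, and 0.24 for alternative activation genes (adjusted p = 0.371), with the arginase gene Arg1 at 1.48 ± 0.32 (adjusted p = 0.118). Complement genes had -0.51 (adjusted p = 0.231), with C1qb at -1.06 ± 0.42 and C1qc at -0.79. Phagocytic receptors had 0.09 (adjusted p = 0.236), with the scavenger receptor Cd36 at 0.69 and the lipopolysaccharide co-receptor Cd14 at 0.09, and lipid and lysosomal genes had 0.11 (adjusted p = 0.473), with galectin gene Lgals3 at -0.20 and cathepsin gene Ctsl at 0.11. For senescence genes the median (-0.002) and the mean (0.30) differed in sign, and camera's direction was up (adjusted p = 0.262), with 1 member higher over all genes and 3 adjusted over the list alone. The arrest gene Cdkn1a had -0.21 ± 0.23. Heat shock genes had -0.28 (adjusted p = 0.638), with the chaperones Hsp90ab1 at 0.01 and Hspa8 at -0.26, and glycolysis genes 0.06 (adjusted p = 0.231), with the enzymes Gapdh at -0.15 and Aldoa at -0.39. Oxidative phosphorylation genes had 0.05 (adjusted p = 0.486), with Cox4i1 at 0.25 and Uqcrh at 0.24, and growth factor genes 0.27 (adjusted p = 0.158), with Thbs1, a matrix glycoprotein, at 1.70 ± 0.42 and Gdf15, a stress-induced member of the TGF-beta family, at 0.44. Ribosomal protein genes had 0.09 (adjusted p = 0.371), with Rps24 at 0.16 and Rpl13 at 0.09. Leaving out a single pair brought 7 of these lists past the threshold, namely the perivascular (adjusted p = 0.00107), alternative activation (0.0304), senescence (0.0304) and growth factor (0.0304) lists without the 26-week pair, and the complement (0.0322), glycolysis (0.00146) and ribosomal (0.0219) lists without the 52-week pair. With all mononuclear phagocytes pooled the phagocytic (median 0.38, adjusted p = 0.00656), lipid and lysosomal (0.20, 0.0226), perivascular (0.50, 0.0120), alternative activation (0.35, 0.0398) and growth factor lists (0.31, 0.0367) passed. The ribosomal list also passed without repeated barcodes (0.25, 0.0229). Over all alternatives the highest adjusted p of the 7 lists that a left-out pair changed was 0.904, 0.888, 0.628, 0.628, 0.836, 0.867 and 0.958 in turn. Cd163, a haemoglobin receptor, had 1, 6, 9, 5, 12 and 37 UMIs and Lyve1, a hyaluronan receptor, 0, 0, 0, 0, 2 and 2, too few to test. The 0 of Lyve1 in the 8-week untreated macrophages allows up to 3 UMIs.

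The third comparison, which the title of the series puts first, asked how macrophages of 52-week skin differed from those of 8-week skin. No gene passed edgeR's test among 2133 (0 higher, 0 lower; smallest adjusted p 0.285), 166 genes had an unadjusted p under 0.05, and DESeq2 called 1 higher and 8 lower. Cd74 had the pattern closest to a fall, with 1636 and 2316 CPM at 8 weeks, 2779 and 5413 at 26 weeks and 690.5 and 1062 at 52 weeks, a log2 change of -1.25 ± 0.28 against 8 weeks (adjusted p = 0.285). Against 26 weeks Cd74 was the 1 gene that fell, by 2.26 ± 0.28 on the log2 scale (adjusted p = 0.0479), and 26 against 8 weeks gave 0 genes (100 at an unadjusted p under 0.05). Other values at 52 against 8 weeks were -1.14 ± 0.30 for Mmp12, macrophage elastase, -0.98 ± 0.32 for H2-Ab1, -0.92 ± 0.40 for Mrc1, -0.69 ± 0.30 for Il1b, -0.56 for Ccl2, -0.45 for Cdkn1a and 0.63 ± 0.37 for Arg1, none past the threshold. In simulation this contrast recovered 78.7% of 4-fold and 9.78% of 2-fold changes. Leaving out single libraries gave 38 genes without the 8-week untreated, 3 without the 8-week PBMC-sec, 74 without the 26-week untreated, 0 without the 26-week PBMC-sec (smallest adjusted p 0.296, 206 genes at an unadjusted p under 0.05), 64 without the 52-week untreated and 94 without the 52-week PBMC-sec library, each with 1 residual degree of freedom.

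For age, 6 of the 19 lists passed camera in macrophages, 2 higher and 4 lower at 52 weeks. The unfolded protein response list was higher, with a median log2 change of 0.77 over 12 members (adjusted p = 2.72e-05, adjusted p = 0.855 with an estimated correlation), 0 members past the threshold over all genes and 4 adjusted over the list alone. Hspa5 had 799 and 426 CPM at 8 weeks against 2235 and 825 at 52 weeks (log2 1.19 ± 0.39), and Ddit3, a stress transcription factor, and Manf, a secreted chaperone, both picked after their values were seen, had 1.84 ± 0.46 and 1.31 ± 0.36. The call was lost with all mononuclear phagocytes pooled (median 0.40, adjusted p = 0.273), over alternatives from 1.31e-09 to 0.855. Ribosomal protein genes were higher by a median of 0.38 over 34 members (adjusted p = 3.80e-06, adjusted p = 0.899 with an estimated correlation), with 0 members past the threshold, Rps24 at 0.36 and Rpl13 at 0.32. That call was lost without the 8-week untreated (0.124) or the 52-week untreated library (0.216), over alternatives from 2.45e-09 to 0.899. The class II list was lower, with a median of -0.66 over 6 members (adjusted p = 0.00439, adjusted p = 0.855 with an estimated correlation), 0 past the threshold over all genes and 2 lower adjusted over the list alone. It was lost without the 8-week untreated (0.318), 8-week PBMC-sec (0.145), 26-week untreated (0.123), 52-week untreated (0.0548) or 52-week PBMC-sec library (0.189), over alternatives from 2.44e-11 to 0.855. The inflammatory list had -0.39 over 22 members (adjusted p = 0.0193, adjusted p = 0.876 with an estimated correlation), with Cxcl2 at -0.38 and Ccl4 at -0.66, and was lost without the 8-week untreated (0.318), 8-week PBMC-sec (0.140) or 52-week untreated library (0.699), over alternatives from 0.000760 to 0.876. The phagocytic receptor list had -0.49 over 9 members (adjusted p = 0.0218, adjusted p = 0.876 with an estimated correlation), with Cd14 at -0.47 and Cd36 at -0.23. It was lost without the 8-week untreated (0.318), 8-week PBMC-sec (0.253), 26-week untreated (0.0564), 52-week untreated (0.193) or 52-week PBMC-sec library (0.189), over alternatives from 0.0103 to 0.876. The immediate early list had -0.39 over 19 members (adjusted p = 0.0160, adjusted p = 0.876 with an estimated correlation), with Zfp36 at -0.997 ± 0.316 and Ier3 at -0.48. It was lost without the 8-week untreated (0.243), 8-week PBMC-sec (0.253) or 52-week untreated library (0.303), over alternatives from 0.00656 to 0.876. Without the low-count filter or with thinned sums the inflammatory (0.0685 and 0.105), phagocytic (0.106 and 0.120) and immediate early lists (0.142 and 0.0824) were lost. The inflammatory list was also lost with unnamed sub-clusters included (0.299). With all mononuclear phagocytes pooled the inflammatory list passed in the other direction (0.65, adjusted p = 0.00266), the phagocytic median was 0.54 (0.130) and the immediate early list was lost (0.115).

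The other 13 lists did not pass for age. Median log2 changes were -0.50 for perivascular resident genes (adjusted p = 0.0833), with Pf4 at -0.89 and Ccl8 at -0.71, -0.13 for class I presentation (0.625) and -0.27 for alternative activation (0.625). Type I interferon genes (0.667) had a median of -0.07, a mean of 0.04 and an upward camera direction, and single libraries decided it, with 0.91 without the 52-week untreated and -0.84 without the 52-week PBMC-sec library, over adjusted p-values of the alternatives from 2.67e-08 to 0.941. The values were -0.46 for complement (0.152), with C1qb at -0.74 and C1qc at -0.82, 0.11 for lipid and lysosomal genes (0.320), -0.12 for senescence (0.667), -0.34 for heat shock (0.313), -0.05 for NRF2 (0.758) and 0.15 for glycolysis (0.313). For oxidative phosphorylation the median was -0.01 and camera's direction up (0.9754), and growth factors and matrix proteases had -0.49 (0.152) and -0.16 (0.672), with Thbs1 at 0.99, Gdf15 at -0.85 and Mmp13, a collagenase, at -0.12. Adjusted over the list alone, 1 member was lower in the senescence and 1 in the NRF2 list. Without the 52-week PBMC-sec library the perivascular (0.0110), complement (0.000407) and glycolysis lists (2.66e-05) passed, and without the 8-week PBMC-sec library the glycolysis list did (0.0327). With all mononuclear phagocytes pooled the interferon (1.02, 9.39e-05), lipid and lysosomal (0.86, 9.39e-05), NRF2 (0.65, 0.000256), glycolysis (0.40, 0.0145) and matrix protease lists (0.45, 0.0145) passed as higher at 52 weeks. Without genes prone to free RNA the perivascular (0.0196), complement (0.0196), senescence (0.0276) and growth factor lists (0.0349) passed as lower. With doublets kept the perivascular (0.0258) and complement lists (0.0106) passed as lower and the glycolysis list as higher (0.0334). The perivascular list passed at 5% mitochondrial UMIs (0.0338) and with unnamed sub-clusters (0.0371), and the growth factor list without the low-count filter (0.0483).

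The untreated libraries alone gave the age series without treatment or holding, as single values with no replicate and no test. Slpi stood at 357, 791 and 2131 CPM at 8, 26 and 52 weeks, a log2 ratio of 2.58 (Poisson 95% interval 2.19 to 2.99), and Vegfa, an angiogenic growth factor, at 77.9, 128 and 322 CPM (2.05, 1.22 to 3.01). Il10, an anti-inflammatory cytokine, stood at 727, 406 and 235 CPM (-1.63, -1.95 to -1.29), Tnip3, an inhibitor of NF-kB signalling, at 364, 107 and 70.7 (-2.36, -2.88 to -1.84), and Ms4a7, a membrane protein of resident macrophages, at 565, 289 and 189 (-1.58, -1.95 to -1.20). Higher at 52 weeks were also the histone gene Hist1h2bc with 39.0, 160.3 and 205 CPM (2.39), the non-coding Gas5 (1.79), Usf2 (1.74) and Gpbp1 (1.67). Rassf8 had 1, 5 and 94 UMIs (3.75, 1.24 to 9.07), Nufip1 2, 2 and 141 (3.34, 1.46 to 6.40), the translocon gene Sec61a1 3, 3 and 117 (2.48, 0.90 to 4.78) and Rpn1, of the glycosylation complex, 3, 5 and 92 (2.14, 0.54 to 4.44). Lower at 52 weeks were the protease gene Mmp19 with 299, 224 and 81.0 CPM (-1.88), the interferon-induced GTPase gene Gbp5 (-1.67), Ehd4 (-1.65), Rapgef2 (-1.61), AW112010 (-1.59), the haem synthesis gene Alas1 (-1.57) and Znfx1 (-1.57). These 20 genes were chosen for the size of their ratio, and sub-cluster 1 held 28.2, 4.41 and 50.9% and sub-cluster 2 45.9, 75 and 12.0% of the macrophages of these libraries. With all mononuclear phagocytes pooled, the log2 ratio of the 10 lower genes summed was -0.24 instead of -1.69, and that of the 10 higher genes 1.89 instead of 2.35. Slpi is also a neutrophil marker, and these libraries held 0, 1 and 127 neutrophils, and the part of neutrophil RNA in its rise was not measured.

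The fourth comparison asked whether the PBMC-sec difference in macrophages changed with age. No gene passed edgeR's test of a linear change with age in weeks (0 of 2133; 98 at an unadjusted p under 0.05), and DESeq2 also called 0. In simulation this test recovered 3.37% of 4-fold changes, so it had little power to find changes of that size. The interferon list's mean log2 CPM, lower in treated macrophages at 8 and 26 weeks and not at 52 weeks, was not tested for a difference between ages.

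Treated and untreated skin also differed in the other classes, and here too the contrast holds PBMC-sec and ex vivo holding together. Their counts of called genes cannot be ranked, since the sums of a library ranged from 11373427 to 29162320 UMIs in keratinocytes and from 54946 to 262143 in pericytes. Akr1b3 rose in keratinocytes (log2 4.82 ± 0.26, adjusted p = 0.000587), fibroblasts (3.18 ± 0.19, 0.000847) and endothelial cells (3.57 ± 0.35, 0.00955). H1f0 rose in T or innate lymphoid cells (2.09 ± 0.26, 0.000405) and endothelial cells (1.41 ± 0.22, 0.0433; 0.0786 without the 8-week pair, the highest over its alternatives). Interferon genes fell in fibroblasts and pericytes, among them Cxcl10, a chemokine for T cells, in fibroblasts (-3.04 ± 0.54), which went from 713 to 30.6, from 153 to 15.3 and from 92.9 to 33.7 CPM. In edgeR 1787 genes passed in keratinocytes (848 higher, 939 lower, of 13199), 285 in fibroblasts (138 and 147, of 11142), 27 in pericytes or smooth muscle cells (13 and 14, of 2938), 25 in T or innate lymphoid cells (11 and 14, of 4221) and 14 in endothelial cells (9 and 5, of 4998). Leaving out 1 pair moved these counts to 1083 in keratinocytes (without the 26-week pair), 23, 86 and 576 in fibroblasts, 8, 65 and 0 in pericytes, 2, 0 and 22 in T or innate lymphoid cells and 26, 36 and 174 in endothelial cells, without the 8-, 26- and 52-week pair in turn.

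The type I interferon list was lower with PBMC-sec in 4 of the 5 other classes. Its median log2 change was -1.56 in fibroblasts (adjusted p = 5.68e-14, 0.434 with an estimated correlation), with 9 of 25 members lower over all genes and 23 adjusted over the list alone, and -1.85 in keratinocytes (5.51e-10, 0.652 with an estimated correlation), with 17 and 21 of 25. In pericytes it was -1.70 (4.38e-23, 0.231 with an estimated correlation), with 9 and 18 of 21, and in endothelial cells -1.49 (6.05e-12, 0.680 with an estimated correlation), with 1 and 15 of 23. In T or innate lymphoid cells it was -0.28 over 6 members (0.419). At 52 weeks the list's mean log2 CPM was 5.92 untreated and 5.53 treated in fibroblasts and 6.26 and 6.19 in endothelial cells. At 8 weeks these classes had 7.37 and 4.86, and 7.60 and 5.87. At 26 weeks they had 6.45 and 4.23, and 7.15 and 5.09. Pericytes had 7.89 and 6.59 at 52 weeks and keratinocytes 3.17 and 1.66. The keratinocyte means were low, from 0.999 to 3.77. In keratinocytes too few members were left to test once genes prone to free RNA were taken out. Named members were Ifit3 (-2.77 ± 0.49) and Rsad2 (-2.22 ± 0.39) in fibroblasts, Ifit3b (-3.67 ± 0.65), Gbp2 (-2.51 ± 0.47), Rsad2 (-2.42 ± 0.42) and Ifit3 (-2.09 ± 0.37) in pericytes and Bst2 (-1.76 ± 0.26) in endothelial cells. In fibroblasts the calls of Cxcl10, Ifit3 and Rsad2 were lost without the 8-week pair (adjusted p = 0.113, 0.158 and 0.143) or the 26-week pair (0.136, 0.125 and 0.130), their highest values over all alternatives being 0.136, 0.158 and 0.143. In pericytes those of Ifit3, Gbp2 and Rsad2 were lost without the 8-week pair (0.153, 0.178 and 0.0899) or the 52-week pair (0.0656, 0.0686 and 0.111), and that of Ifit3b without the 8-week pair (0.0899), also the highest over its alternatives.

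Antioxidant genes were higher in the same classes. The NRF2 list had a median of 0.69 in fibroblasts (adjusted p = 2.59e-07, 0.434 with an estimated correlation), with 6 of 23 members higher over all genes and 14 higher and 1 lower adjusted over the list alone, and 0.26 in keratinocytes (0.0117, 0.652 with an estimated correlation), with 5 and 6 of 23. In pericytes it had 0.48 (0.00737, 0.516 with an estimated correlation) and in endothelial cells 0.50 (8.92e-05, 0.680 with an estimated correlation). Nqo1, a quinone reductase, rose in fibroblasts (2.46 ± 0.21), Srxn1, sulfiredoxin, in endothelial cells (1.80 ± 0.22) and Gclc, of glutathione synthesis, in pericytes (1.75 ± 0.39, lost without the 8-week pair at 0.194 and the 52-week pair at 0.470, the highest over its alternatives). The inflammatory list was higher in fibroblasts (median 0.57, adjusted p = 0.000359, 0.434 with an estimated correlation; 0 members over all genes, 8 adjusted over the list alone), pericytes (0.76, 0.000996, 0.362 with an estimated correlation; 3 and 7) and endothelial cells (0.79, 0.000285, 0.680 with an estimated correlation; 1 and 6). The unfolded protein response list was lower in fibroblasts (-0.72, 8.65e-07, 0.434 with an estimated correlation; 3 and 12 of 20 members lower), pericytes (-0.46, 0.00172, 0.362 with an estimated correlation) and endothelial cells (-0.49, 0.000285, 0.680 with an estimated correlation). It was not lower in keratinocytes, where its mean log2 CPM untreated and treated was 6.27 and 6.32, 6.24 and 6.52, and 6.49 and 6.70 by age. T or innate lymphoid cells had 7.37 and 7.28, 7.31 and 7.37, and 7.68 and 7.73. In keratinocytes 5 lists passed as higher and 3 as lower, and not all of them are named here. The unnamed cluster led by genes of this list belonged to none of these classes. Class I presentation was lower in fibroblasts (-0.95, 3.60e-06, 0.434 with an estimated correlation; 4 and 6 of 13 members lower). In keratinocytes proliferation genes were higher (0.49, 4.84e-06, 0.652 with an estimated correlation; 8 of 22 over all genes, 11 adjusted over the list alone), as were ribosomal protein genes (0.54, 4.22e-06, 0.652 with an estimated correlation; 0 members) and differentiation genes (0.21, 0.0269, 0.664 with an estimated correlation; 3 and 3 of 25). The wound keratinocyte list did not pass (0.25, 0.0601; 5 higher and 1 lower over all genes, 8 and 1 adjusted over the list alone). These keratinocyte values mix changes inside clusters with shifts between clusters. The largest keratinocyte cluster held 2987, 121, 258, 82, 272 and 21 cells, and another held 51, 439, 106, 732, 22 and 434. In fibroblasts proliferation genes were lower (-0.52, 3.60e-06, 0.434 with an estimated correlation; 3 and 9 of 18), as were collagen and elastic fibre genes (-0.38, 0.00124, 0.473 with an estimated correlation; 3 lower over all genes, 12 lower and 1 higher adjusted over the list alone). A fibroblast cluster led by Col3a1 and Col1a1 held 40, 8, 10, 0, 445 and 29 cells, and its part in the collagen fall was not tested. Cholesterol genes did not pass in fibroblasts (0.11, 0.259) or keratinocytes (0.05, 0.523), nor did endothelial activation genes (0.966), whose median was -0.002 and mean 0.08. Without the 52-week pair the inflammatory list of fibroblasts (median 0.29, adjusted p = 0.111), their collagen list (0.0586) and the NRF2 (0.19, 0.0869) and differentiation lists (-0.02, 0.475) of keratinocytes no longer passed. Without the 8-week pair the NRF2 (0.05, 0.604) and inflammatory lists (0.25, 0.0512) of pericytes did not pass, nor did their unfolded protein response list without the 26-week pair (-0.24, 0.0771) or with thinned sums (-0.30, 0.0908). Without genes prone to free RNA the NRF2 (0.24, 0.108) and differentiation lists (0.20, 0.0656) of keratinocytes and the inflammatory list of endothelial cells (0.06, 0.114) were lost. The differentiation list was also lost without repeated barcodes (0.18, 0.0562). Leaving out the 8-, 26- and 52-week pair in turn moved the count of lists from 13 to 12, 12 and 6 in fibroblasts and from 8 to 8, 9 and 5 in keratinocytes. It moved from 9 to 4, 6 and 10 in pericytes, from 6 to 4, 8 and 5 in endothelial cells and from 0 to 2, 0 and 0 in T or innate lymphoid cells.

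Further genes named by the rule were as follows in each class. In T or innate lymphoid cells the histone gene Hist1h2bc (2.78 ± 0.29), the granzymes Gzmb (2.72 ± 0.39) and Gzmc (2.13 ± 0.42) and the apoptosis inhibitor Birc3 (2.16 ± 0.36) rose, and the phosphatase gene Ptpn6 (-1.91 ± 0.32) and stress factor Atf3 (-1.27 ± 0.26) fell, with 0 of these calls left without the 26-week pair. In fibroblasts the heat shock protein gene Hspa4l (2.19 ± 0.17), the histone gene Hist1h1c (2.11 ± 0.19) and Trdc, a T cell receptor gene (2.85 ± 0.35), rose and the exonuclease gene Isg20 (-2.17 ± 0.23) and the matrix gene Thbs4 (-2.09 ± 0.26; adjusted p = 0.0561 without the 8-week pair, the highest over its alternatives) fell. Thbs4 was a leading gene of a fibroblast cluster with 40, 8, 10, 0, 445 and 29 cells. Trdc was not called prone to free RNA, but that rule compares a class with all other cells together. It can miss RNA of a rare class such as T cells, and the source of Trdc was not tested. In keratinocytes Tslp, an epithelial cytokine (2.52 ± 0.39), Lce3e, of the cornified envelope (2.74 ± 0.50), and Pinlyp (2.33 ± 0.14) rose and Dapl1 (-2.23 ± 0.44) and the chaperone Hspa1a (-1.68 ± 0.19) fell. Nppb (2.90 ± 0.27) was a leading gene of a keratinocyte cluster with 51, 439, 106, 732, 22 and 434 cells, and Mmp9 (-3.20 ± 0.44) and Gjb6 (-1.73 ± 0.18) of a cluster with 221, 8, 122, 2, 72 and 10 cells, and these 3 were not tested within clusters. In pericytes Hist1h2bc (2.89 ± 0.41), Hspa4l (1.92 ± 0.36), the nuclear RNA Neat1 (1.53 ± 0.25) and Hspa1a (1.37 ± 0.22) rose and galectin gene Lgals9 (-2.10 ± 0.43) fell. Without the 8-week pair the adjusted p was 0.0938 for Hspa4l and 0.225 for Lgals9, and without the 52-week pair 0 genes of this class passed. In endothelial cells Cd34, a surface sialomucin (1.89 ± 0.26), and Procr, the protein C receptor (1.32 ± 0.21; adjusted p = 0.0842 without the 26-week pair, the highest over its alternatives), rose and Lyve1, a lymphatic marker (-3.61 ± 0.41), and Aebp1 (-1.90 ± 0.30) fell. Aebp1 was a leading gene of a fibroblast cluster, and the part of fibroblast RNA in its fall was not tested. No cluster was named lymphatic endothelial, and the endothelial cluster of 818 cells had that class as its second score (0.684). Whether the fall of Lyve1 reflects fewer lymphatic cells in this class was not tested.

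In the age test 48 genes passed in T or innate lymphoid cells (23 higher and 25 lower at 52 than at 8 weeks), 6 in fibroblasts, 3 in pericytes and 0 in keratinocytes and endothelial cells. In T or innate lymphoid cells Cd163l1, a receptor of dermal gamma-delta T cells, rose from 4.52 and 32.3 CPM at 8 weeks to 252 and 264.9 at 52 weeks (log2 4.13 ± 0.60, adjusted p = 0.00377). The sums of this class held 221009 and 123732 UMIs at 8 weeks and 87251 and 207594 at 52 weeks. The 8-week values of Cd163l1 therefore rest on few UMIs. The chemokine receptor gene Cxcr4 (3.17), Fyco1 (3.07), Bcl2a1b, an inhibitor of apoptosis (3.04), and the receptor gene Il18r1 (2.75) rose, and Tcrg-V5, the receptor segment of epidermal gamma-delta T cells (-2.06 ± 0.39), the T cell receptor component Cd3g (-1.78), cathepsin W (Ctsw, -1.69) and Nkg7 (-1.57) fell. Cd3g and Nkg7 were leading genes of the larger T cell cluster, which held 119, 116, 168, 148, 36 and 69 cells against 17, 17, 40, 69, 16 and 62 in the smaller. The part of this shift between clusters in the changes of Cd163l1, Tcrg-V5 and the other genes was not tested. Except for Cd163l1, each of these genes lost its call without the 52-week PBMC-sec library, with adjusted p-values of 0.0769 (Tcrg-V5) to 0.475 (Bcl2a1b). Without the 8-week PBMC-sec library those of Cxcr4 and Il18r1 were 0.693, the highest over their alternatives, and the count moved to 78, 30 and 167 without the 8-week untreated, 8-week PBMC-sec and 52-week untreated libraries. In fibroblasts Igfbp4, a binding protein of insulin-like growth factors, rose (2.41 ± 0.24, adjusted p = 0.0389). The other 5 called genes lay outside the rule and were chosen after their values were seen, with Cdkn2a, a cell cycle inhibitor (3.97 ± 0.44), Tagln (3.41 ± 0.42), Scube3 and F5 higher and Plbd1 lower. With RLE size factors 3 of the 6 fibroblast calls were kept. The fibroblast cluster led by Col3a1 and Col1a1 held 40, 8, 10, 0, 445 and 29 cells, and its part in these 6 changes was not tested. In pericytes Cxcl10 rose (2.37 ± 0.38, adjusted p = 0.0377; 0.0537 without the 8-week untreated and 0.0959 without the 52-week untreated library, the highest over its alternatives), beside Ccl19 (higher) and Fabp5 (lower), both prone to free RNA. At an unadjusted p under 0.05 there were 3499 genes in keratinocytes and 321 in endothelial cells, and DESeq2 called 437 higher and 248 lower in keratinocytes and 1 higher and 7 lower in endothelial cells. Leaving out single libraries gave 35 to 1937 genes in keratinocytes, 6 to 81 in endothelial cells, 4 to 700 in fibroblasts and 8 to 52 in pericytes.

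Some lists passed camera for age in these classes. Cholesterol genes were lower at 52 weeks in T or innate lymphoid cells (median -1.35 over 13 members, adjusted p = 3.88e-06, 0.552 with an estimated correlation; 0 over all genes, 5 adjusted over the list alone), in endothelial cells (-0.72, 0.00188, 0.830 with an estimated correlation) and in fibroblasts (-0.39, 0.00149, 0.643 with an estimated correlation). The unfolded protein response list was higher in fibroblasts (0.52, 5.69e-05, 0.643 with an estimated correlation) and T or innate lymphoid cells (0.34, 0.0419, 0.552 with an estimated correlation) and lower in endothelial cells (-0.43, 0.00250, 0.830 with an estimated correlation). In fibroblasts collagen and elastic fibre genes were higher (0.47, 0.000148, 0.643 with an estimated correlation; 0 over all genes, 12 higher and 2 lower adjusted over the list alone), and a cluster led by Col3a1 and Col1a1 held 445 of the 1004 fibroblasts of the 52-week untreated library. In keratinocytes proliferation genes were lower (-0.68, 7.31e-05, 0.827 with an estimated correlation; 0 over all genes, 13 of 22 adjusted over the list alone), and the wound (0.59, 0.0238, 0.827 with an estimated correlation; 0 and 2 of 24) and differentiation lists (0.51, 0.0238, 0.827 with an estimated correlation; 0 and 0) were higher. In both lists the rise lay between the PBMC-sec libraries alone. A keratinocyte cluster led by Epgn and Cldn4 held 9, 41, 24, 83, 48 and 650 cells, and its part in the rise was not tested. Mean log2 CPM at 8 and 52 weeks was 8.29 and 8.30 untreated and 8.18 and 9.07 with PBMC-sec for the wound list, and 8.45 and 8.39 and 8.31 and 9.16 for the differentiation list. Without the 52-week PBMC-sec library their medians were -0.04 and 0.08 (0.788 for both), and without the 8-week PBMC-sec library the adjusted p was 0.0755 and 0.522. Ribosomal protein genes were also higher in keratinocytes (0.26, 0.0238, 0.827 with an estimated correlation), and passed in the other direction without the 52-week PBMC-sec library (-0.28, 0.00392). In endothelial cells the interferon (-0.54, 0.00307, 0.932 with an estimated correlation) and inflammatory lists (-0.53, 0.0138, 0.830 with an estimated correlation) were lower, and in pericytes heat shock genes were higher (0.46, 0.0157, 0.693 with an estimated correlation). Leaving out single libraries ended further calls. The unfolded protein response list of T or innate lymphoid cells (0.0530 to 0.315) and the heat shock list of pericytes (0.0851 to 0.264) did not pass without any 1 of the 6. The collagen list of fibroblasts did not without the 8-week untreated library (0.0829). In endothelial cells these 4 lists were also lost without that library, at 0.538 for cholesterol, unfolded protein response and inflammatory genes and 0.632 for interferon genes. Without the 52-week untreated library the interferon list passed in the other direction (0.19, 0.0237), and without the 52-week PBMC-sec library the inflammatory (0.612) and unfolded protein response lists (0.151) were lost. Without genes prone to free RNA the inflammatory list of endothelial cells (-0.14, 0.574) and the unfolded protein response list of T or innate lymphoid cells (0.31, 0.0962) did not pass, and the cholesterol lists had too few members to test. The inflammatory list was also lost without the low-count filter (-0.61, 0.0735), as was the ribosomal list of keratinocytes (0.26, 0.0585). With thinned sums the heat shock list of pericytes was lost (0.27, 0.148) and the cholesterol list of T or innate lymphoid cells could not be tested. Without repeated barcodes the unfolded protein response list of the latter was lost (0.22, 0.206). No list of these classes passed with an estimated correlation or with fry, for which the counts were 0.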

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

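The 3 tests of the macrophage share were chosen after the share had been seen. Macrophage-like cells, which clear debris and regulate inflammation in skin, made up 11.1 times as large a share of untreated cells at 52 as at 8 weeks, and 3.45 times with PBMC-sec. Among cells other than keratinocytes the ratios were 4.22 and 3.07, the latter with a lower 95% bound of 2.22, which argues against fewer keratinocytes at 52 weeks as the whole cause. Without the repeated barcodes of the 8-week untreated library the untreated ratio was 8.57 (lower bound 6.21), which argues against these barcodes as the whole cause. Inflamed or wounded skin in the 52-week pools stays open, since neutrophils were also more frequent there. The wound keratinocyte list had a median log2 change of 0.59 over 24 members, a call lost with an estimated correlation (adjusted p = 0.827). Its mean log2 CPM rose with PBMC-sec (8.18 to 9.07) and not in untreated skin (8.29 and 8.30), where the macrophage share differed most. Age itself may equally explain the difference. With 1 pool of 3 animals per condition, these cannot be told apart.

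Neutrophils stood outside the comparisons and exceeded the limit that a count of 0 allows in both 52-week libraries. They made up 3.56% of untreated cells (127 cells, 95% interval 2.98 to 4.22) and 0.654% of PBMC-sec cells (31 cells, 0.445 to 0.927). The other 4 libraries held 0, 1, 1 and 1, and the 0 of the 8-week untreated library allows up to 0.0352%.

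The unnamed phagocyte sub-cluster 4 was also seen at 52 weeks and in no other library, with 1.49% of untreated cells (53 cells, 1.12 to 1.94) and 1.88% of PBMC-sec cells (89 cells, 1.51 to 2.31). It was led by Ccl4, Arg1, Rsad2 and Ifnb1, the gene of interferon beta. The class left for it was macrophage (score 0.565, 9 markers raised). It stayed unnamed because its 10 leading genes held 1 neutrophil marker and 0 macrophage markers. Its 142 cells were therefore outside the macrophage shares and the main macrophage tests.

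The macrophage share moved with PBMC-sec in opposite directions at different ages, by log2 0.70 at 8 weeks and -0.98 at 52 weeks, from 1 pair each. The fall at 52 weeks came mostly from sub-cluster 1, with 200 untreated and 39 treated cells, whose name is less certain. Without it the values were 1.03 and -0.19, and the intervals of the 2 shares at 52 weeks overlapped (4.69 to 6.21% and 4.16 to 5.39%). This difference was not tested.

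In T or innate lymphoid cells the PBMC-sec difference changed with age for 24 genes (17 higher and 7 lower with age), of which Sdc4 among the higher and Cxcl1, Fabp5, Krt16 and Ly6d among the lower were prone to free RNA. Cx3cr1, the fractalkine receptor, had 2797 CPM in untreated and 38.5 CPM in treated cells at 52 weeks, a change of -6.72 log2 units over 44 weeks (adjusted p = 3.05e-05). Many of the others were ribosomal protein genes, such as Rps28 with 2.46 (adjusted p = 0.00283). The 52-week libraries held 52 and 131 cells of this class. In pericytes or smooth muscle cells 1 gene changed, Col1a1, a collagen gene of fibroblasts prone to free RNA, with 2415 and 50.8 CPM at 52 weeks. In endothelial cells the 8 genes included Lypd3, Sbsn and Serpinb2, which keratinocytes express, and all 8 were prone to free RNA. These genes were chosen after their values were seen.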

How the results depend on the processing

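Of the 718 values of named macrophage genes for treatment under alternatives, 684 kept direction and side of the threshold, 14 no longer passed and 20 newly passed. For age 768 of 800 kept both, 30 newly passed and 2 reversed. Of the list values, 261 of 304 for treatment and 299 of 361 for age kept both. In other classes 451 of 525 gene values did and 74 no longer passed. Of the 42 macrophage shares 28 stayed within their intervals. Values past the threshold in neither fit counted as kept whatever their sign (20 of 718, 56 of 800, 10 of 304 and 30 of 361). The removal of repeated barcodes, the unnamed sub-clusters, and for other classes the omission of single libraries for age and all list alternatives, and shares without sub-cluster 1, were chosen after seeing the data.

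With all mononuclear phagocytes pooled, age values reversed for Cd36 (1.17), Mmp13 (1.25) and the inflammatory (0.65), phagocytic (0.54), NRF2 (0.65) and matrix protease lists (0.45). The interferon list, whose median (-0.07) and upward test differed in sign, had 0.91 without the 52-week untreated and -0.84 without the 52-week PBMC-sec library. Apart from tests of fewer or more genes or libraries, the cause was not tested.

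The 9 treatment genes of macrophages became 22 with DESeq2, 89 without the low-count filter, 14 without genes prone to free RNA, 31 at 5% mitochondrial UMIs, 22 with doublets kept, 14 pooled and 3 without the age block. The 0 age genes became 9 with DESeq2, 62 without the filter, 13 with doublets kept, 417 pooled and 28 with unnamed sub-clusters. The 0 genes of treatment by age became 20 without the filter. The 8 and 6 lists became 0 and 0 with an estimated correlation and with fry, and the 6 age lists (2 higher, 4 lower) 3 with thinned sums, 10 without genes prone to free RNA and 9 with doublets kept. With all mononuclear phagocytes pooled they were 12 for treatment (9 higher, 3 lower) and 9 for age (7 higher, 2 lower). Lists of other classes also became 0 with both tests. For treatment, the 0 lists of T or innate lymphoid cells became 3 without the filter and 2 with thinned sums, the 13 of fibroblasts 9 without genes prone to free RNA, the 8 of keratinocytes 12 without the filter and 4 without genes prone to free RNA (3 lower to 1), and the 9 of pericytes 6 with thinned sums. For age, 2 became 1 (thinned sums), 0 (without genes prone to free RNA) and 1 (without repeated barcodes) in T or innate lymphoid cells, 5 became 8 (no filter) in fibroblasts, 7 became 4 (no filter) and 9 (without prone genes or repeated barcodes) in keratinocytes, 2 became 0 (thinned sums) in pericytes and 6 became 4 (without prone genes) in endothelial cells. Apart from left-out pairs and libraries, other list counts moved by at most 1.

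DESeq2 gave 14 and 25 genes in T or innate lymphoid cells (treatment, age), 63 in fibroblasts and 685 in keratinocytes (age), 14 in pericytes (treatment), and 23 and 8 in endothelial cells. No low-count filter gave 41 and 88 in T or innate lymphoid cells, 1139 and 524 in fibroblasts, 1536 in keratinocytes (age), 72 and 50 in pericytes and 220 and 88 in endothelial cells. Without genes prone to free RNA there were 11 and 26 in T or innate lymphoid cells, 228 in keratinocytes (age), and 86 and 1 in endothelial cells. Without repeated barcodes there were 48 and 30, 11 in fibroblasts (age), 257 in keratinocytes (age), 43 and 11 in pericytes and 128 and 14 in endothelial cells. RLE factors gave 3 in fibroblasts and 0 in pericytes (age). Thinned sums gave 9 in pericytes (age) and 26 and 7 in endothelial cells.

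Leaving out pairs gave 8 to 24 treatment genes in macrophages, 0 to 22 in T or innate lymphoid cells, 23 to 576 in fibroblasts, 1083 to 2286 in keratinocytes, 0 to 65 in pericytes and 26 to 174 in endothelial cells. Leaving out libraries gave 0 to 94, 30 to 167, 4 to 700, 35 to 1937, 8 to 52 and 6 to 81 age genes. Macrophage lists ranged from 5 to 9 and from 1 to 8. In the other classes, in the same order, they ranged from 0 to 2, 6 to 12, 5 to 9, 4 to 10 and 4 to 8 for treatment and from 1 to 5, 4 to 11, 4 to 7, 0 to 1 and 0 to 7 for age. In the untreated libraries the summed log2 ratio of the 10 higher genes (2.35) was 1.89 pooled, and that of the 10 lower genes (-1.69) was -1.48 with TMM and -0.24 pooled.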

Other observations

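For the ribosomal list, the test of keratinocyte RNA and the split of the whole-library test by treatment were chosen after their values had been seen. Some genes moved alike with PBMC-sec in several classes. Akr1b3, the aldose reductase gene, rose in macrophages, fibroblasts, keratinocytes and endothelial cells, and in pericytes it rose by log2 2.23 ± 0.44 (adjusted p = 0.0206, prone to free RNA there). In T or innate lymphoid cells it had 0.83 ± 0.37 (adjusted p = 0.584). H1f0 also rose in fibroblasts (2.09 ± 0.18, adjusted p = 0.00251) and keratinocytes (1.28 ± 0.16, 0.00488), and Fxyd2 in fibroblasts (3.82 ± 0.25, 0.000925). Pericyte shares were higher with PBMC-sec in 3 of 3 pairs (log2 2.09, 0.74 and 0.63, exact permutation p = 0.25), as were Langerhans cell shares (0.80, 0.26 and 0.77, exact permutation p = 0.25). That p is the smallest that 3 pairs allow. Without repeated barcodes the 8-week values were 1.37 for pericytes and 0.22 for Langerhans cells.

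The type I interferon list was lower with PBMC-sec in macrophages, with a median log2 change of -0.87 over all 3 ages, a call lost with an estimated correlation (adjusted p = 0.628). Its mean log2 CPM was lower at 8 and 26 weeks but not at 52 weeks (8.18 untreated, 8.34 treated), so the tests below concern the change fitted over all ages. Over the 18 of 21 members with a higher CPM in macrophages than in all other cells, the median was -0.74 (quartiles -1.14 and -0.49), which argues against free RNA as the whole cause. With sums thinned to 1 total it was -1.05 (17 members, quartiles -1.74 and -0.51). Thinning keeps each gene's expected part of the sum and leaves depth per cell as it was. It therefore cannot decide whether depth played a part. Of the 3 untreated libraries 0 were held ex vivo, so PBMC-sec may lower these genes or holding may do so, and both cannot be told apart. Sub-cluster 5, with Rsad2 among its 10 leading genes, held 11.8, 2.38, 7.35, 2.56, 12.0 and 18.6% of macrophages. The part that sub-cluster weights played in the fall was not tested.

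The ribosomal protein list was higher at 52 weeks in macrophages, with a median of 0.38 over 34 members. That call was lost with an estimated correlation (adjusted p = 0.899) and without the 8-week untreated (0.124) or the 52-week untreated library (0.216). Leaving out genes prone to free RNA removed none of these 34, so that test, fixed beforehand, told nothing and was replaced. At 8 weeks the members had a higher CPM in keratinocytes than in macrophages, by a median log2 of 1.24 untreated (quartiles 0.98 and 1.57) and 1.26 with PBMC-sec (0.91 and 1.60). Less keratinocyte RNA would then lower the list, which argues against it as the cause. The fitted median was above 0 in 4 of the 5 other classes. Between the untreated libraries, where macrophages rose by 0.62, it was above 0 in 1 of 5, with T or innate lymphoid cells at -0.48, keratinocytes at -0.35 and fibroblasts at -0.25. That argues against a shift of whole libraries there. Between the PBMC-sec libraries it was above 0 in 4 of 5 and macrophages had 0.19, so such a shift may contribute in treated skin. Within sub-clusters the median ratio was 0.41 over 5 comparisons that ranged from -0.53 to 0.57, a spread too wide to settle the part played by sub-cluster weights. Age itself stays open and untested.

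The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The treatment split gave 9 genes in macrophages against at most 1 in another split, 285 against 0 in fibroblasts, 1787 against 0 in keratinocytes, 27 against 10 in pericytes and 14 against 0 in endothelial cells, with 1 of 10 splits as large in each. In T or innate lymphoid cells it gave 25 against 26 and for macrophage lists 8 against 9, with 3 of 10 splits as large. These other splits are not free of treatment. With age as a block, 6 of the 9 keep 2 pairs whole, so they measure treatment within 1 pair and come as 3 couples of equal counts. The highest counts above 0 all came from the 52-week pair. The other 3 part all pairs with 1 of them turned round, and gave at most 0 genes in every class and 5 lists.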
